A study of Mus musculus with 20 samples.

How the data were processed

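The series holds RNA-seq of mouse oocytes and early embryos from 2 experiments. In the Btg4 experiment, libraries labelled Btg4-/- and wild type were made at 4 stages: the germinal vesicle (GV) oocyte, which is arrested in the first meiotic prophase, the mature oocyte arrested in metaphase of the second meiotic division (MII), the zygote, and the 2-cell embryo. Each of these 8 groups has 2 libraries, 16 in all. In the Erk experiment, GV and MII oocytes labelled Erk-/- and wild type gave 4 libraries, 1 per group. Per the labels, each sample pooled 60 oocytes or embryos from females 21 to 23 days old. Per the same labels, mRNA was purified before library preparation, and libraries were sequenced in paired-end mode on an Illumina HiSeq instrument. Groups and replicate numbers were taken from the sample titles alone.

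The deposited files give gene-level FPKM (fragment counts scaled by transcript length and by the number of mapped fragments) for 23813 loci per library, with gene symbols, mm9 coordinates, an interval around each estimate and a status flag. Per the submitters' processing notes the tools were CASAVA 1.8, TopHat and Cufflinks with the mm9 genome. The versions of TopHat and Cufflinks and the annotation release are not given in the sources used here. FPKM values as the authors deposited them are relative: a transcript class that takes a larger share of a library lowers all others. They also depend on transcript length, and an mRNA purified by its poly(A) tail can change in FPKM through a change in tail length without a change in amount. Loci that share a symbol were summed (260 symbols with more than 1 locus), which left 23309 symbols. Of these, 175 carry the status LOWDATA, where Cufflinks marks its estimate as too complex or too shallow; they were kept. Reads of near-identical gene copies (ribosomal protein genes and their processed pseudogenes, Nlrp9, Obox, Tdpoz, Zscan4 and Usp17l families, histone genes) can be split between copies by Cufflinks, so values of single members are uncertain. No locus lies on the mitochondrial chromosome in the files used here.

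Depth was estimated from the deposited intervals, taken as 4 SDs wide, over genes whose intervals correspond to 20 to 500 fragments. It came to 2900000 to 5300000 fragments per library in the Btg4 experiment and 6140000 to 8730000 in the Erk experiment. Ratios of the smallest steps between low FPKM values gave similar relative depths, for example 0.71 by steps and 0.72 by intervals for wild-type 2-cell library 2 relative to wild-type GV library 1. These intervals cover counting error only. Replicates differed by more than that: the median squared difference between the 2 libraries of a group was 2.62 to 7.63 times the value that the intervals alone predict, so no library pair was treated as a duplicate.

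Comparisons were made on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a group-means model over all 16 libraries of the Btg4 experiment (8 residual degrees of freedom) and moderated variances with a trend on mean expression. Log2 changes on this scale understate the change of genes near or below 1 FPKM. Genes entered when their mean was at least 1 FPKM in at least 1 of the 8 groups, which left 12311 genes. P-values are two-sided, adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05. The contrasts were Btg4-/- against wild type at each stage, each stage against the previous one within each genotype, and the difference between genotypes in each of these steps. Beside them, 2 sets of genes that passed the threshold in wild type were followed in the libraries labelled Btg4-/-. These were genes that fell at least 2-fold from GV to MII and genes that rose at least 2-fold from zygote to 2-cell. The wild-type changes that chose them do not use the labelled Btg4-/- libraries. Those libraries entered the choice only through the expression filter and the shared variance of the fit.

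Lists of genes fixed before the data were examined were tested with camera (preset correlation 0.01) on the same design, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. There were 18 lists: the CCR4-NOT deadenylase complex with BTG/TOB adaptors, other mRNA decay and poly(A) factors, oocyte-secreted and zona pellucida genes, maternal effect genes, meiotic and mitotic cell cycle regulators, dormant maternal mRNAs recruited in maturation, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, mitochondrially encoded mRNAs, proteasome subunits, translation factors, ribosome biogenesis genes, 2-cell zygotic activation genes, p53 targets and apoptosis genes, ERK pathway immediate-early and feedback genes, and markers of granulosa and cumulus cells, of sperm and of blood cells. The mitochondrially encoded list has 0 members in the files used here and gave no result. Counts of members are given over all genes tested and adjusted over the list alone. The list tests from zygote to 2-cell were added to those planned.

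Genes named in the text follow a rule that was also fixed in advance. It takes Btg4 (Mapk3 for the Erk experiment), the 8 largest rises and 8 largest falls per genotype comparison (5 each way for MII against GV) among genes past the threshold with a mean of at least 10 FPKM in either group and no overlap between the libraries of the groups, leaving out predicted genes, and up to 4 passing members of each list. For the Erk experiment the same rule was applied to the size of the change alone. With 1 library per group no test was made there. Genes with at least 5 FPKM in either library were compared, 2-fold changes were counted, and the median of each list was placed among 10000 random lists of the same size drawn from 20 bins of matched mean expression (seed 11). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and for the plots.

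The limma and camera steps were run on simulated data before use, with noise drawn independently for each gene. The camera step was thus not tested with correlated genes, and the estimated correlation of ribosomal proteins here was 0.181. For the MII genotype comparison with 12311 genes, 200 of them changed, 57% of the 2-fold and 96% of the 4-fold changes were recovered, with 11 false calls (6.71% of calls), 0 calls of the wrong sign, and 0 calls by limma in the unchanged GV comparison.

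The results of the Btg4 experiment were recomputed with pseudocounts of 0.1 and 5, without the expression filter and with a filter at 5 FPKM, with median-of-ratios scaling (5432 genes above 1 FPKM in all 16 libraries), with quantile normalization, on the libraries of the compared groups alone, with the replicate number as a block, without the variance trend, and without each library in turn. The list tests were not repeated without the trend. The Erk results were recomputed with both pseudocounts, from 1 FPKM and with median-of-ratios scaling. After the data were seen, 3 more were added: the list tests without each library in turn, a fit without the GV libraries (for gene results only), and a correction for transcript length, in which a lowess trend (span 0.3) of each library's deviations on log length was removed. Lengths came from the GENCODE M21 annotation, matched by symbol only (87.3% of the symbols, 91.8% of the genes tested); none of its coordinates were used, because it is on another genome build.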

Results

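The data are FPKM values of RNA-seq libraries from mouse oocytes and embryos of the ICR strain. The Btg4 experiment has 16 libraries, 2 for each genotype at the GV, MII, zygote and 2-cell stages, and the Erk experiment has 4, 1 for each genotype at GV and MII. Estimated depth was 2900000 to 5300000 fragments per library in the former and 6140000 to 8730000 in the latter. Between 8385 and 10058 symbols reached 1 FPKM in a library of the Btg4 experiment and between 7265 and 9253 in one of the Erk experiment. Pearson r between the 2 libraries of a group, across genes on the log2 scale, was 0.924 to 0.974. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Unless stated otherwise, values are mean FPKM ± SD of 2 libraries, log2 changes are on the log2(FPKM + 1) scale, and adjusted p-values are from limma.

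Btg4 encodes an adaptor that couples the CCR4-NOT deadenylase to the translation machinery in maturing oocytes, and the question was which transcripts depend on it from the GV oocyte to the 2-cell embryo. The targeted gene itself (chromosome 9, 50924106 to 50927805, mm9) was measured in every library. At GV it stood at 1980 and 1881 FPKM in the libraries labelled Btg4-/- and at 1450 and 1673 in wild type (log2 change 0.31, adjusted p = 0.138). At MII it was lower in the labelled Btg4-/- libraries, 172 and 191 against 415 and 406 FPKM (log2 change -1.18, adjusted p = 2.61e-06), and in the zygote it was 139 and 164 against 610 and 560 (-1.94, adjusted p = 5.71e-08). At the 2-cell stage it was higher, 3514 and 3632 against 1147 and 964 FPKM (1.76, adjusted p = 9.62e-08). Gene-level FPKM cannot show the loss of part of a gene and the allele is not given in the labels, so these values check the labels only in part. Because the gene was not lower at GV and was higher at 2-cell, groups are called here by their labels.

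**Figure D1:**
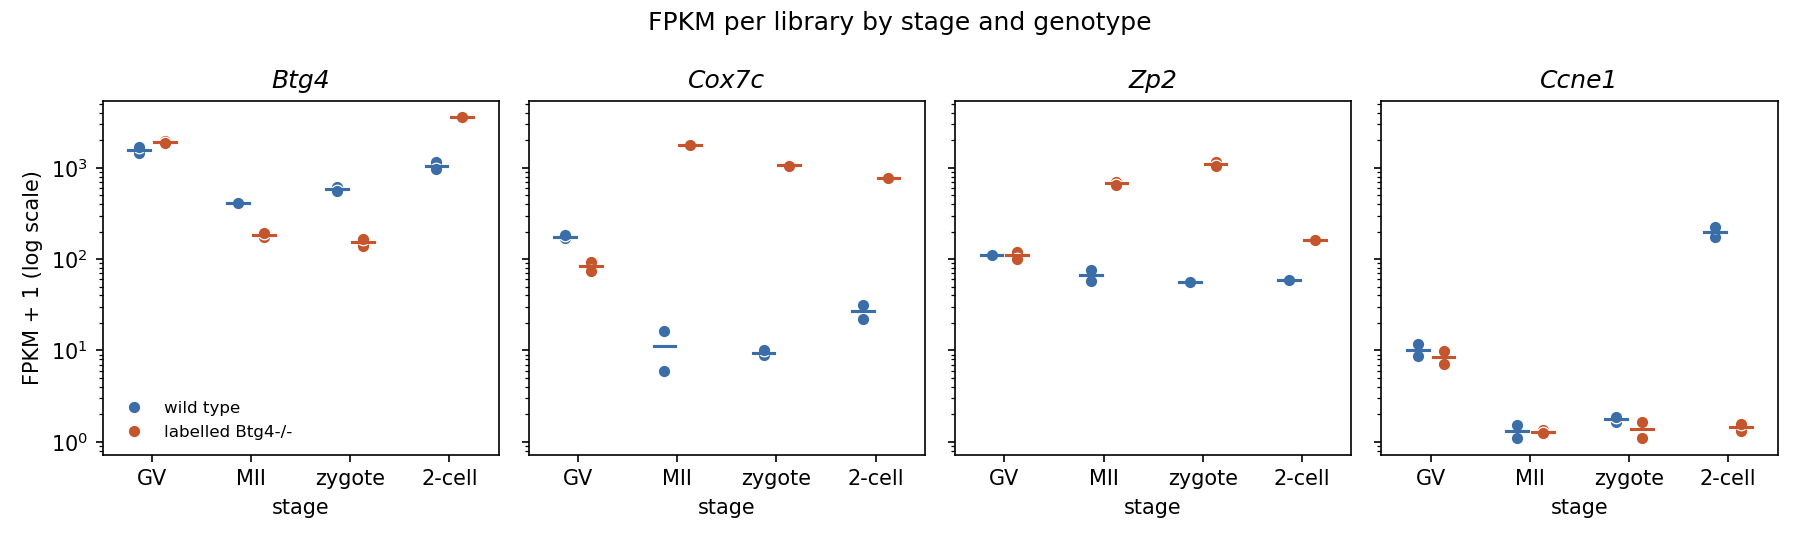
FPKM + 1 on a log axis by stage for Btg4, Cox7c, Zp2 and Ccne1; points are single libraries (blue wild type, orange labelled Btg4-/-) and bars are means of 2 libraries. At MII Cox7c had means of 1769 FPKM in the labelled Btg4-/- libraries and 10.2 in wild type, and at the 2-cell stage Ccne1 had means of 0.434 and 199.

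At GV, before meiotic resumption, single genes of the oocyte differed in the libraries labelled Btg4-/-. Gdf9, the oocyte growth factor that acts on granulosa cells, was at 488 ± 60.1 FPKM against 957 ± 67.8 in wild type (SD, n = 2; log2 change -0.97, adjusted p = 0.000685). Astl, the cortical granule protease that cleaves ZP2, was at 12.8 ± 1.62 against 39.2 ± 0.244 (-1.55, adjusted p = 0.000599). The kinase gene Mapk3, which encodes ERK1, was lower as well (11.7 ± 2.9 against 32.3 ± 4.74, -1.40, adjusted p = 0.000583), as was the securin gene Pttg1 (86.7 ± 17 against 223 ± 7.25, -1.37, adjusted p = 0.00245). Higher genes included the nuclear long non-coding RNA Malat1 (chromosome 19, 5795690 to 5802671; 41.4 ± 4.38 against 3.06 ± 1.01, 3.40, adjusted p = 2.59e-05), the cytokine receptor gene Il20ra (42.7 ± 3.37, listed at 0 in both wild-type libraries) and the oocyte-secreted list's Plac1l (295 ± 22 against 133 ± 14.9, 1.14, adjusted p = 0.00341). The oocyte-secreted list had 1 higher and 4 lower of 10 (2 and 6 adjusted over the list alone) and did not pass (median -0.51, adjusted p = 0.0883, range over the alternatives 0.00647 to 0.304). It passed as lower with quantile normalization, the length correction, the replicate block and no filter, and without labelled Btg4-/- library 1 (0.0495). Of the maternal effect genes, whose products the early embryo inherits, 1 was higher (Nlrp9c, 41.6 ± 4.72 against 22.1 ± 0.0289), 11 were lower and 28 did not pass (1 and 14 adjusted over the list alone). The lower members included Dnmt3l, a cofactor of de novo DNA methylation (5.89 ± 0.482 against 14.6 ± 3.21, adjusted p = 0.00226).

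Over all genes, 178 were higher and 795 lower at GV in the labelled Btg4-/- libraries, out of 12311. The median of all genes was -0.12 and moved to 0 with median-of-ratios scaling, under which the split was 369 higher and 400 lower (48% higher, against 18.3% as deposited). Quantile normalization gave 38.6% and the length correction 40.4% higher. Single libraries also moved these counts: without labelled Btg4-/- library 1 or 2 or wild-type library 1 or 2, the higher genes were 82, 89, 53 or 62, and the lower genes were 216, 209 and 265 without the last 3 of these. The maternal effect list as a whole was lower (median -0.35, camera adjusted p = 0.0164, range over the alternatives 0.00191 to 0.225; adjusted p = 0.577 with an estimated correlation), and the call ended with median-of-ratios scaling, the length correction, the filter at 5 FPKM and the fit on the GV libraries alone, and without wild-type library 1 (0.0585). Cytosolic ribosomal proteins were higher as a list (median 0.11, adjusted p = 0.00266, range 1.66e-06 to 0.369; adjusted p = 0.772 with an estimated correlation). Of its members, 3 were higher, 1 lower and 75 did not pass (0 and 0 adjusted over the list alone). The call ended with quantile normalization and the length correction, and without labelled Btg4-/- library 1 (0.335, median -0.036) or wild-type library 2 (0.0518). Proteasome and oxidative phosphorylation subunits passed as higher with median-of-ratios scaling (adjusted p = 0.00375 and 0.0294) and without labelled Btg4-/- library 2 (0.0258 and 0.0418). Decay and poly(A) factors passed as lower without that library (0.0491) and with no filter (0.0407). The granulosa cell gene Inhba was 41.4 ± 7.24 FPKM in the labelled Btg4-/- GV libraries and 14.0 ± 2.92 in wild type (adjusted p = 0.00505; 0.316 with a pseudocount of 0.1, 0.0525 without labelled Btg4-/- library 2 and 0.0588 without wild-type library 1). It was the 1 member of 13 granulosa markers to pass. With the fit on the GV libraries alone limma called 0 genes, with 2956 at an unadjusted p under 0.05, and the named calls above ended (Gdf9 adjusted p = 0.0982, Malat1 0.089).

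At MII, components of ribosomes, of the respiratory chain and of the proteasome were higher in the libraries labelled Btg4-/-. Cox7c, a cytochrome c oxidase subunit (chromosome 13, 86184403 to 86186400), was at 1769 ± 22.9 FPKM against 10.2 ± 7.33 in wild type (SD, n = 2; log2 change 7.49, adjusted p = 3.2e-09), and Sdhd, a subunit of succinate dehydrogenase, at 704 ± 11 against 10.4 ± 0.357 (5.95, adjusted p = 3.34e-12). The proteasome core subunits Psmb7 (1337 ± 59.3 against 16.3 ± 5.69) and Psmb1 (469 ± 15 against 8.55 ± 0.0626) and the ribosomal proteins Rpl18 (558 ± 43.4 against 15.9 ± 4.49) and Rpsa (221 ± 5.21 against 4.61 ± 1.4) were likewise higher. Of 79 ribosomal proteins measured, 69 were higher, 0 lower and 10 did not pass (70 and 0 adjusted over the list alone; median 2.18). Of 79 oxidative phosphorylation subunits, 63 were higher and 2 lower (64 and 2 adjusted over the list alone; median 1.98), and of 37 proteasome subunits 21 were higher and 5 lower (22 and 5 adjusted over the list alone; median 1.19). With the length correction these medians were 1.36, 1.25 and 0.60. These lists passed camera with adjusted p = 6.65e-18, 7.31e-13 and 0.0012. With an estimated correlation none did (adjusted p = 0.128, 0.128 and 0.268 with an estimated correlation).

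Several regulators of mRNA tails and decay were lower at MII. Cnot6l, a catalytic deadenylase of the CCR4-NOT complex (chromosome 5, 96504757 to 96591009), was at 28.3 ± 3.98 FPKM in the labelled Btg4-/- libraries against 258 ± 12 (SD, n = 2; log2 change -3.15, adjusted p = 8.56e-09). Pan3, the cofactor of the Pan2 deadenylase, was at 3.95 ± 1.53 against 57.1 ± 4.89 (-3.59, adjusted p = 2.6e-08), Pabpn1l, a poly(A)-binding protein of the oocyte, at 56.7 ± 11.5 against 453 ± 5.67 (-2.99, adjusted p = 7.09e-09), and Pabpc1 at 6.07 ± 2.44 against 37.3 ± 6.47. Of 34 such decay and poly(A) factors, 7 were higher and 18 lower (7 and 20 adjusted over the list alone; median -0.86, camera adjusted p = 0.00904, range 0.00305 to 0.104; adjusted p = 0.268 with an estimated correlation). The call ended with the length correction, where the median was -0.46. Dormant maternal mRNAs, which are stored in the GV oocyte and polyadenylated in maturation, had 5 higher, 10 lower and 4 not passing (5 and 11 adjusted over the list alone; median -0.57, adjusted p = 0.0165; adjusted p = 0.268 with an estimated correlation). Their median was -0.89 with median-of-ratios scaling, -1.02 with quantile normalization and -1.06 with the length correction. Among the lower ones were Tet3, the dioxygenase that oxidises methylated cytosine in the zygote (5.98 ± 0.143 against 69.4 ± 1.18), and the spindle factor Tpx2 (1.99 ± 0.522 against 13.5 ± 1.03). The CCR4-NOT list itself had 3 higher and 6 lower members of 16 and did not pass (adjusted p = 0.177).

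Genes that make and mark the oocyte went both ways. The zona pellucida gene Zp2 (chromosome 7, 127275875 to 127288804) was at 674 ± 27.4 FPKM in the labelled Btg4-/- MII libraries against 65.3 ± 13.2 (SD, n = 2; log2 change 3.36, adjusted p = 1.42e-09) and Fgf8 at 121 ± 3.43 against 16.7 ± 3.93. Kit, the receptor of the growing oocyte, was at 8.89 ± 0.331 against 79.2 ± 10.8 (-3.01, adjusted p = 1.19e-08). In this list 5 members were higher and 4 lower, and its median of 0.43 turned to -0.08 with quantile normalization and -0.48 with the length correction (adjusted p = 0.699 as deposited). Maternal effect genes divided similarly, 15 higher and 17 lower of 40 (adjusted p = 0.699). Khdc3, of the subcortical maternal complex, was at 2163 ± 34.3 against 112 ± 10.1 (4.27, adjusted p = 2.08e-09) and Zar1l at 792 ± 65.5 against 30.8 ± 4.47 (4.65). Cell cycle regulators had 13 higher and 19 lower of 50 (adjusted p = 0.3), among the latter the cyclin gene Ccnb2 (9.53 ± 1.75 against 72.7 ± 2.18) and the cohesin subunit gene Smc3 (1.41 ± 1.14 against 26.0 ± 2.25). Of the largest falls, the DNA topoisomerase gene Top1 was at 4.08 ± 0.298 against 111 ± 10.7 (-4.46, adjusted p = 1.08e-09) and Sycp3, of the synaptonemal complex, at 0.787 ± 0.484 against 43.8 ± 10.1. Haemoglobin transcripts also differed: Hba-a1 was at 0.575 ± 0.813 FPKM in the labelled Btg4-/- MII libraries and 55.3 ± 15.3 in wild type (-5.24, adjusted p = 1.18e-06), with 1.11 ± 0.659 in wild-type GV.

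Over all genes, 3585 were higher and 2870 lower at MII, with 2880 and 2167 of them beyond 2-fold. Summed FPKM was 477225 and 472082 in the labelled Btg4-/- MII libraries and 357517 and 379914 in wild type, and the ribosomal RNA precursor Rn45s was at 11696 and 10929 against 20984 and 16014 FPKM. The share of higher among called genes was 55.5% as deposited and 46.4% with median-of-ratios scaling. No list other than those 5 passed at MII, except granulosa and blood cell markers, which were lower without wild-type library 2 (adjusted p = 0.0471 and 0.0217); translation factors had 25 higher and 18 lower of 61 (adjusted p = 0.504), and p53 and apoptosis genes 6 and 3 of 21 (adjusted p = 0.699).

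**Figure D2:**
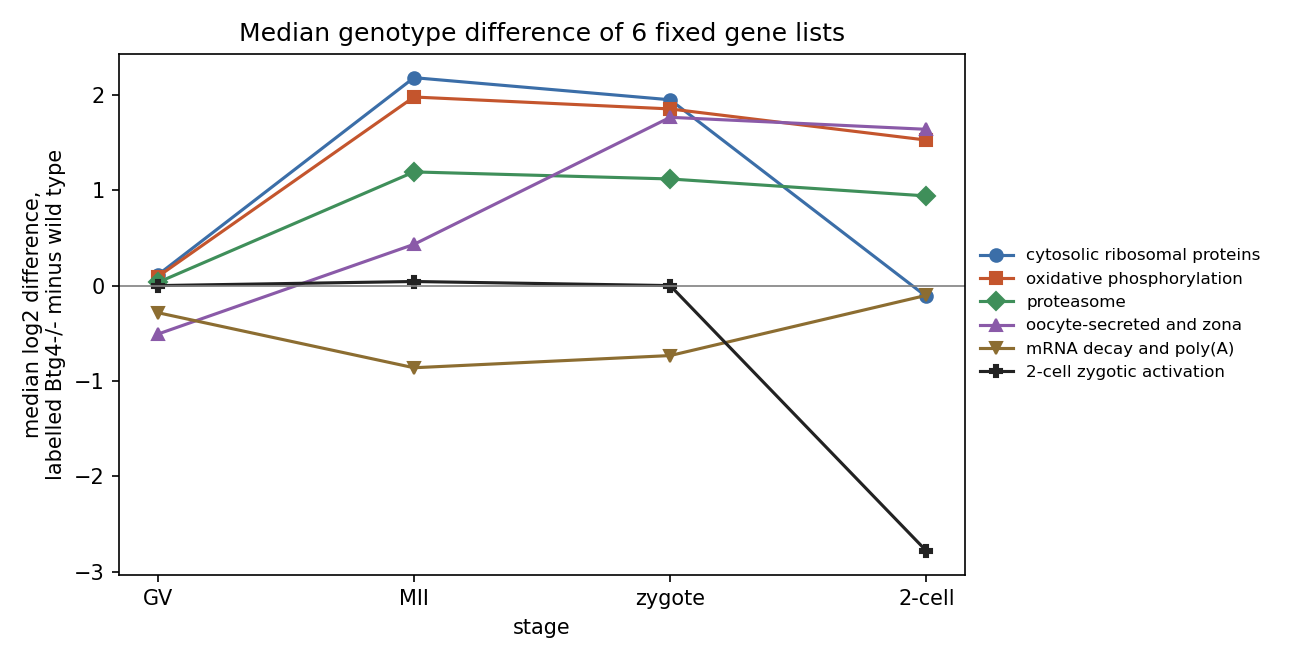
Median log2 change (labelled Btg4-/- minus wild type, log2(FPKM + 1) scale) at the 4 stages for 6 gene lists, with a line at 0; each point is the median over the measured members of a list. Ribosomal proteins lie at 2.18 at MII and 1.95 in the zygote and at -0.11 at 2-cell, where zygotic activation genes lie at -2.78; with the length correction the medians of the oocyte-secreted list at MII (-0.48), of the zygotic activation list at MII (-0.38) and of the decay factors at 2-cell (0.14) have the opposite sign.

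In the zygote, transcripts of ribosomes, the respiratory chain and the proteasome were higher in the libraries labelled Btg4-/-. Cox7c was at 1064 ± 23.3 FPKM in the labelled Btg4-/- libraries against 8.41 ± 0.836 (SD, n = 2; log2 change 6.83, adjusted p = 1.12e-08). Khdc3 (chromosome 9, 72950205 to 72952250) was at 1938 ± 155 against 23.7 ± 5.76 (6.31, adjusted p = 2.21e-10), and Dppa5a, a germ cell and pluripotency marker, at 1473 ± 25.2 against 17.2 ± 3.35 (6.35, adjusted p = 2.21e-10). Khdc3 is a maternal effect gene, and that list went both ways, with 10 higher, 13 lower and 17 not passing (11 and 14 adjusted over the list alone; median 0.008, mean 0.04, camera direction down, adjusted p = 0.958). Mos, the kinase that holds the MII arrest through ERK, was at 269 ± 10.8 against 35.2 ± 8.79 (2.92, adjusted p = 3.69e-07). Lower genes included Top1 (8.25 ± 0.706 against 252 ± 4.06, -4.78, adjusted p = 1.03e-09) and the pre-ribosomal factor Mphosph10 (5.85 ± 1.87 against 186 ± 23.6, -4.79, adjusted p = 3.1e-08). Also lower were the translation initiation factor Eif2s2 (54.7 ± 1.91 against 848 ± 37.2, -3.93) and the insulator gene Ctcf (8.16 ± 1.35 against 76.3 ± 15.8, -3.07).

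By list, 64 ribosomal proteins were higher and 1 lower in the zygote (67 and 1 adjusted over the list alone), 61 oxidative phosphorylation subunits were higher and 3 lower (61 and 3 adjusted over the list alone), and 23 proteasome subunits were higher and 4 lower (23 and 6 adjusted over the list alone). Their medians were 1.95, 1.85 and 1.12, with camera adjusted p = 1.6e-21, 3.4e-15 and 1.09e-05, and adjusted p = 0.0815, 0.0815 and 0.167 with an estimated correlation. The zona and oocyte-secreted list was higher with 7 against 2 members (7 and 2 adjusted over the list alone; median 1.77, adjusted p = 0.00993, range 0.00228 to 0.0569; adjusted p = 0.285 with an estimated correlation). It included Zp2 (1097 ± 64.1 against 55.1 ± 0.00679) and Zp3 (718 ± 105 against 76.0 ± 5.78), while Oosp1, an oocyte-secreted protein gene, was lower (261 ± 32.4 against 1502 ± 272). Decay and poly(A) factors had 4 higher and 20 lower (7 and 20 adjusted over the list alone; median -0.73, adjusted p = 0.0259, range 0.0127 to 0.199; adjusted p = 0.285 with an estimated correlation), with Pan3 (6.55 ± 0.0312 against 53.1 ± 1.38) and the translational repressor gene Pum2 (5.61 ± 0.814 against 26.9 ± 2.43) among the lower. The zona call ended in the fit on the zygote libraries alone (0.0569), and the decay factor call with the filter at 5 FPKM (0.0561) and the length correction (0.199). With the length correction the proteasome median was 0.59 and that of the decay factors -0.46.

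In all, 2999 genes were higher and 2872 lower in the zygote (51.1% higher; 43.2% with median-of-ratios scaling). Of the genes higher at MII, 2362 were also higher in the zygote, where independent lists of these sizes would share 873, and 2128 were lower at both stages against 670. Pearson r between the genotype changes at these stages was 0.812 across genes, which are not independent replicates. The stages share no library.

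The 2-cell comparison asked how the embryonic genome's first transcripts fared, since activation of the zygotic genome falls at this stage in the mouse. Genes of that wave were lower in the libraries labelled Btg4-/-. Of 33 zygotic activation genes 29 were lower and 2 higher (30 and 2 adjusted over the list alone; median -2.78, camera adjusted p = 1.73e-11; adjusted p = 0.0793 with an estimated correlation). The histone demethylase gene Kdm5b was at 0.276 ± 0.0301 FPKM against 27.0 ± 3.59 in wild type (SD, n = 2; log2 change -4.45, adjusted p = 2.08e-08) and the multicopy gene Tdpoz5 at 3.76 ± 2.24 against 144 ± 24.6. Ribosome biogenesis genes, needed for the nucleolus of the embryo, had 14 lower and 1 higher of 32 (14 and 1 adjusted over the list alone; median -0.83, adjusted p = 0.00306; adjusted p = 0.206 with an estimated correlation). Among them, Polr1c, a subunit of RNA polymerases I and III, was at 1.38 ± 0.0759 against 59.5 ± 16.3 and the nucleolar methyltransferase gene Fbl at 8.29 ± 2.01 against 67.7 ± 20.6. Cell cycle regulators went both ways, with 17 higher and 14 lower of 50 (17 and 16 adjusted over the list alone; median 0.09, and -0.17 with median-of-ratios scaling; mean -0.08, adjusted p = 0.517). Of these, Ccne1, which encodes cyclin E1 (chromosome 7, 38883003 to 38892509), was at 0.434 ± 0.175 FPKM against 199 ± 32.5 in wild type (SD, n = 2; log2 change -7.12, adjusted p = 2.57e-09), and Cdk1, the mitotic kinase gene, at 0.928 ± 0.347 against 45.1 ± 8.49 (-4.58, adjusted p = 1.3e-08). The tetraspanin gene Cd63 was listed at 0 in both labelled Btg4-/- libraries and at 183 ± 42.1 in wild type. The p53 list had 3 higher and 11 lower of 21 (3 and 12 adjusted over the list alone) and did not pass as a whole (adjusted p = 0.0651; 0.0483 without labelled Btg4-/- library 1 and 0.0436 without wild-type library 2). Its lower members included the stress gene Sesn2 (0.891 ± 1.15 against 76.5 ± 26.8) and the cell cycle inhibitor gene Cdkn1a (1.18 ± 0.92 against 25.9 ± 0.428).

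Oocyte transcripts were higher at this stage in the labelled Btg4-/- embryos. Gdf9 was at 1059 ± 81.7 FPKM against 184 ± 10.3 (SD, n = 2; log2 change 2.52, adjusted p = 6e-09) and Plac1l at 945 ± 64.4 against 25.3 ± 6.32 (5.19, adjusted p = 7.73e-10). Zar1, which binds and stores maternal mRNA (chromosome 5, 72968353 to 72972323), was at 435 ± 21.9 against 22.6 ± 5.46 (4.23, adjusted p = 1.31e-09), and Padi6, of the cytoplasmic lattices, at 530 ± 8.39 against 52.7 ± 8.09. In the zona and oocyte-secreted list 9 of 10 were higher and 1 lower (9 and 1 adjusted over the list alone; median 1.64, and 1.004 with quantile normalization; adjusted p = 1.93e-05, and adjusted p = 0.0793 with an estimated correlation). Of the maternal effect genes 22 were higher, 7 lower and 11 not passing (23 and 7 adjusted over the list alone; median 0.58, adjusted p = 0.000138, range 7.38e-06 to 0.0568 with quantile normalization; adjusted p = 0.0793 with an estimated correlation). Their median was 0.29 with median-of-ratios scaling and 0.36 with quantile normalization. Oxidative phosphorylation subunits, 53 higher and 7 lower (55 and 7 adjusted over the list alone; median 1.53, adjusted p = 3.59e-11), and proteasome subunits, 23 higher and 3 lower (24 and 4 adjusted over the list alone; median 0.94, adjusted p = 7.15e-07), were higher too. Each had adjusted p = 0.0793 with an estimated correlation. Examples were Ndufb3 at 296 ± 46.2 against 5.66 ± 3.86 and Psma7 at 660 ± 23.4 against 50.4 ± 0.312. Dormant maternal mRNAs had 10 higher and 4 lower (10 and 4 adjusted over the list alone; median 0.39, adjusted p = 0.046, range 0.0127 to 0.775; adjusted p = 0.272 with an estimated correlation), a call that ended with median-of-ratios scaling, quantile normalization, the filter at 5 FPKM and the fit on the 2-cell libraries alone, and without labelled Btg4-/- zygote library 1 (0.05) or 2-cell library 2 (0.0568).

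Ribosomal protein transcripts went both ways at 2-cell, with 26 higher, 29 lower and 24 not passing (26 and 30 adjusted over the list alone). Rpl22 was at 125 ± 18.3 FPKM against 15.1 ± 3.64 (SD, n = 2), and Rpl10l at 1.70 ± 1.38 against 65.1 ± 6.39. The list's median was -0.11, its mean -0.14 and its camera direction up (adjusted p = 0.964), but it was called lower with quantile normalization (median -0.51, adjusted p = 0.00938) and with the length correction (-0.47, adjusted p = 0.0463). Across all genes 2785 were higher and 3252 lower, with a median of -0.05 that moved to -0.26 with median-of-ratios scaling; the higher share was 46.1% as deposited and 35.1% with that scaling. With the fit on the 2-cell libraries alone the counts were 1640 and 1795. The granulosa cell genes Amhr2 and Gja1 were listed at 0 in both labelled Btg4-/- libraries, with Amhr2 at 11.5 ± 0.327 in wild type. The granulosa and cumulus markers did not pass as a list (median 0, camera adjusted p = 0.537). Of the genes lower at 2-cell, 739 were also lower at MII, where independent lists would share 758, and of the higher genes 1324 were higher at MII as well, against 811.

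From GV to MII the question was which transcripts are cleared in maturation and whether they are cleared without Btg4. In wild type, the lactate dehydrogenase gene Ldhb went from 51.2 ± 4.09 to 2895 ± 92.1 FPKM (SD, n = 2; log2 change 5.80, adjusted p = 1.49e-11) and Gnas, a G protein subunit gene, from 6.35 ± 1.04 to 634 ± 162 (6.42, adjusted p = 2.44e-10). Rps15 fell from 1304 ± 3.15 to 12.1 ± 0.489 (-6.64, adjusted p = 1.43e-09) and Plat, the tissue plasminogen activator, a dormant mRNA, from 846 ± 3.6 to 27.6 ± 0.168 (-4.89, adjusted p = 2.72e-10). Ribosomal proteins fell as a list (4 rose and 70 fell, 4 and 70 adjusted over the list alone; median -3.31, camera adjusted p = 2.26e-22; adjusted p = 0.0737 with an estimated correlation). Oxidative phosphorylation subunits fell too (12 rose and 50 fell, 12 and 53 adjusted over the list alone). Their median was -1.88, and -1.16 with the length correction (camera adjusted p = 1.51e-06, and adjusted p = 0.228 with an estimated correlation). Proteasome subunits also fell (7 rose and 24 fell, likewise 7 and 24 adjusted over the list alone). Their median was -1.10 (camera adjusted p = 0.00059, and adjusted p = 0.228 with an estimated correlation). Maternal effect genes rose, 28 against 8 that fell (29 and 8 adjusted over the list alone). Their median was 1.42 (camera adjusted p = 2.06e-05, and adjusted p = 0.0737 with an estimated correlation). Nlrp5, for example, went from 2.37 ± 1.43 to 39.9 ± 0.864. In the wild-type pair of the Erk experiment, with 1 library per stage, this list fell instead (26 lower and 5 higher of 36 at 2-fold, median -2.02). Granulosa markers had 1 rising and 7 falling of 13 and did not pass (1 and 7 adjusted over the list alone; median -1.02, adjusted p = 0.135), among them the inhibin subunit gene Inha, which fell from 45.9 ± 3.03 to 1.65 ± 1.15.

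In the libraries labelled Btg4-/- Ldhb also rose, from 45.8 ± 5.64 to 3045 ± 124 FPKM (log2 change 6.03, adjusted p = 9.16e-12), and so did Padi6, from 60.9 ± 6.26 to 1796 ± 40.5, and Zp2, from 109 ± 14.2 to 674 ± 27.4. The homeobox gene Obox1 (from 1554 ± 80.8 to 27.9 ± 4.56, -5.76, adjusted p = 4.31e-12) and the CCR4-NOT deadenylase gene Cnot7 (from 688 ± 29.5 to 40.2 ± 4.91, -4.07), fell (SD, n = 2). Maternal effect genes rose here too (26 and 2 lower, 28 and 2 adjusted over the list alone; median 0.86, adjusted p = 5.12e-06; adjusted p = 0.0574 with an estimated correlation). Ribosomal proteins fell in 44 cases and rose in 13 (48 and 13 adjusted over the list alone; median -0.85, adjusted p = 1.73e-06; adjusted p = 0.443 with an estimated correlation). Oxidative phosphorylation subunits had 32 higher and 19 lower and did not pass (adjusted p = 0.823), with a median of 0.44 that became -0.004 with median-of-ratios scaling. Granulosa markers fell as a list (1 higher, 9 lower of 13, and 1 and 9 adjusted over the list alone; median -1.20, adjusted p = 0.000609; adjusted p = 0.232 with an estimated correlation), with Inhba listed at 0 in both labelled Btg4-/- MII libraries. The difference between the genotypes did not pass for this list (adjusted p = 0.126; 0.0253 without wild-type MII library 2).

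The difference between the genotypes in this step was itself tested. It was positive for 3263 genes and negative for 1967, a positive share of 62.4% that was 47.2% with median-of-ratios scaling. The median difference over all genes was 0.22 and went to 0 under that scaling. Ribosomal proteins (60 positive and 0 negative, 62 and 0 adjusted over the list alone; median 2.11, adjusted p = 1.42e-14) and oxidative phosphorylation subunits (55 and 0, 58 and 0 adjusted over the list alone; median 1.98, adjusted p = 2.52e-11) stood out on the positive side, each with adjusted p = 0.206 with an estimated correlation. With the length correction their medians were 1.25 and 1.15. For the 2867 genes that fell at least 2-fold in wild type (median -1.89, by their choice), the median change in the labelled Btg4-/- oocytes was -0.47 (quartiles -1.49 and 0.40). Of these, 1159 (40.4%) passed as lower and 458 (16%) as higher, and the difference between genotypes passed as positive for 1740 (60.7%). With median-of-ratios scaling the median in the labelled Btg4-/- oocytes was -0.83, and with the length correction -0.78. The difference shares its wild-type libraries with the choice of the set; the change in the labelled Btg4-/- libraries does not. In wild type 3099 genes rose and 3506 fell from GV to MII, and in the labelled Btg4-/- libraries 3362 and 2223 (60.2% rose; 45.1% with median-of-ratios scaling).

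From MII to zygote fewer genes changed, 2521 up and 985 down in wild type and 1271 and 662 in the labelled Btg4-/- libraries. The wild-type split depended on scaling, with 71.9% up as deposited, 59.3% with median-of-ratios scaling and 51.8% with quantile normalization, and the median of all genes of 0.22 went to 0.10 with the former. In the labelled Btg4-/- libraries 65.8% were up, and 51.1% with the length correction. The change differed between the genotypes for 1503 genes, 610 positive and 893 negative (40.6% positive; 56.4% with quantile normalization). Single libraries moved these counts. In wild type 2015 genes changed without zygote library 2, against 3506, and 1161 in the fit on the compared groups alone. In the labelled Btg4-/- libraries, with 1933 changed genes, 1012 and 1006 were left without MII library 1 or 2, 1086 and 801 without zygote library 1 or 2, and 659 in the fit on the compared groups. The differing genes were 874 without labelled Btg4-/- MII library 2, 899 and 908 without labelled Btg4-/- zygote library 1 or 2, and 959 and 967 without wild-type zygote library 1 or 2.

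From zygote to 2-cell, wild-type embryos gained Ccne1, from 0.763 ± 0.174 to 199 ± 32.5 FPKM (SD, n = 2; log2 change 6.82, adjusted p = 2.11e-09). They lost Zar1, from 1472 ± 179 to 22.6 ± 5.46 (-5.98, adjusted p = 5.51e-11), and the spindle checkpoint kinase gene Bub1b, from 242 ± 6.53 to 3.16 ± 0.146 (-5.87, adjusted p = 4.04e-12). Zygotic activation genes rose (27, with 5 falling, 27 and 5 adjusted over the list alone; median 3.66, camera adjusted p = 1.48e-09; adjusted p = 0.14 with an estimated correlation). Maternal effect genes fell (31, with 4 rising, 31 and 4 adjusted over the list alone; median -1.54, adjusted p = 3.46e-07), a call that held with adjusted p = 0.0357 with an estimated correlation. Ribosomal proteins rose, 62 against 6 (63 and 6 adjusted over the list alone; median 1.46, adjusted p = 1.06e-11; adjusted p = 0.14 with an estimated correlation). In the labelled Btg4-/- embryos Cks2, a cyclin-dependent kinase subunit gene, rose from 17.4 ± 6.84 to 2311 ± 139 (7.03, adjusted p = 1.01e-09) and Oosp1 from 261 ± 32.4 to 5104 ± 58.3 (4.29, adjusted p = 1.66e-10), while Mos fell from 269 ± 10.8 to 16.2 ± 0.838. There 11 zygotic activation genes rose and 7 fell and the list did not pass (median 0.34, adjusted p = 0.209), and ribosomal proteins fell (39, with 6 rising, 42 and 7 adjusted over the list alone; median -0.69, adjusted p = 0.00386; adjusted p = 0.731 with an estimated correlation).

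For the 2619 genes that rose at least 2-fold over this step in wild type (median 1.83, by their choice), the median change in the labelled Btg4-/- embryos was 0.06 (quartiles -0.38 and 0.93), and 0.12, 0.21 and 0.24 with median-of-ratios scaling, quantile normalization and the length correction. It was 0.081 without wild-type zygote library 2, 0 and 0.013 without labelled Btg4-/- 2-cell library 1 or 2, and 0.036 and 0.092 without wild-type 2-cell library 1 or 2. Of these, 703 (26.8%) passed as higher and 375 (14.3%) as lower, and for 1886 (72%) the difference between the genotypes passed as negative. That difference shares its wild-type libraries with the choice of the set, which favours negative values. Over all genes 3342 rose and 3723 fell in wild type, 2250 and 3470 in the labelled Btg4-/- embryos, and the change differed for 5913 genes. The median of all genes for this step moved by 0.15 with median-of-ratios scaling in wild type and by 0.11 in the labelled Btg4-/- embryos.

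The Erk experiment put the same question to oocytes labelled Erk-/-. It has 1 library per group, so its differences have no replicate check. Mapk3 (chromosome 7, 133903140 to 133909330) was at 52.3 FPKM in the library labelled Erk-/- against 333 in wild type at GV and at 34.3 against 25.7 at MII. Btg4 went from 216 at GV to 2987 at MII in wild type and from 250 to 1565 in the labelled Erk-/- pair. It fell from GV to MII in wild type of the Btg4 experiment (log2 change -1.92, adjusted p = 2.88e-08). At MII the library labelled Erk-/- held more of the oocyte's own transcripts: Zp2 at 450 FPKM against 78.7, Zp1 at 305 against 60.0, Nlrp14 at 1461 against 87.6, Padi6 at 727 against 58.7, and Npm2, a histone chaperone, at 268 against 27.0. Cox7c (167 FPKM) and Uqcrq (114 FPKM) were listed at 0 in the wild-type MII library. Lower genes included the histone gene Hist1h2bj (0.369 against 49.7) and the telomerase inhibitor gene Pinx1 (0.612 against 30.1). Values of 0 also occurred at GV, in both directions. There Snhg9 was at 280 FPKM in the library labelled Erk-/- against 0 in wild type, and Ifitm3 at 0 against 183. With 1 library per group, a value of 0 cannot be told from a transcript that the library missed.

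At MII 2041 genes were at least 2-fold higher and 528 lower in the library labelled Erk-/- among 6317 compared. The median of 0.26 became -0.07 with median-of-ratios scaling, which gave 1695 and 964, so that the higher share of these genes was 79.4% as deposited and 63.7% with scaling. Maternal effect genes (19 higher, 0 lower of 36; median 1.05), zona and oocyte-secreted genes (6 and 0 of 10; 1.47), ribosomal proteins (41 and 6 of 72; 1.36) and oxidative phosphorylation subunits (37 and 3 of 69; 1.27) each had a median at percentile 100 of 10000 matched random lists. Proteasome subunits (13 and 1 of 26; 0.99) were at percentile 99.4. These medians stayed positive with median-of-ratios scaling, at 0.72, 1.12, 1.03, 0.94 and 0.67. At GV 1487 genes were higher and 1837 lower of 8240, and oxidative phosphorylation subunits had 9 higher and 22 lower (median -0.37, percentile 0), with Ndufa6 at 9.39 FPKM against 213.

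From GV to MII the median change of 7923 genes in the wild-type library pair was -1.29, and -0.86 with median-of-ratios scaling, with 1716 genes up and 4273 down at 2-fold; for the labelled Erk-/- pair it was -0.51, with 1718 up and 3157 down. Maternal effect genes were lower at MII in 26 cases and higher in 5 of 36 in wild type (median -2.02, percentile 0), and in 10 and 4 of 37 in the labelled Erk-/- pair (-0.24, percentile 21.2). Dormant maternal mRNAs were higher in 12 and lower in 5 of 19 in wild type (1.53, percentile 99.7), and higher in 10 and lower in 3 of 18 in the labelled Erk-/- pair (1.19, percentile 99.8). The genes that fell in wild type of the Btg4 experiment, 2322 of them measured here, changed by a median of -2.32 in wild type and -1.06 in the labelled Erk-/- pair, while 6556 other genes changed by -0.77 and -0.17. Between the genotypes at MII the set was at 0.47, with 920 higher and 183 lower at 2-fold, and the other genes at 0.27.

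The MII changes of the experiments, which share no library, were compared over 6278 genes. Pearson r was 0.423 and Spearman rho 0.407 across genes, which are not independent replicates. Of the genes 2-fold higher in the library labelled Erk-/-, 1171 (57.5%) were also called higher in the libraries labelled Btg4-/-, where independent lists would share 633. For lower genes the overlap was 187 against 186. There were 277 genes higher in the former and lower in the latter, against 736 for independent lists.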

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

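Of the tests weighed here, those of the correlation after the length correction and of the ratio of falls at the 2-cell stage were set before their results were seen, and the others, some of which replaced other versions given below, were chosen only afterwards.

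The effect of genotype differed between stages in tests of the difference itself, for 5230 genes between GV and MII, 1503 between MII and zygote and 5913 between zygote and 2-cell. From GV to MII the list medians of this difference were 2.11 for ribosomal proteins (adjusted p = 1.42e-14) and 1.98 for oxidative phosphorylation subunits (adjusted p = 2.52e-11), each with adjusted p = 0.206 with an estimated correlation. The median was 1.13 for proteasome subunits (20 positive and 4 negative, 20 and 4 adjusted over the list alone; adjusted p = 0.00514, and 0.29 with an estimated correlation). It was -0.91 for decay and poly(A) factors (8 and 14, 9 and 15 adjusted over the list alone; adjusted p = 0.0237, and 0.29 with an estimated correlation), and -0.88 for dormant maternal mRNAs (5 and 10, 5 and 10 adjusted over the list alone; adjusted p = 0.0178, and 0.29 with an estimated correlation). The proteasome and decay factor calls ended with the length correction (adjusted p = 0.131 and 0.157).

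Among Btg4 and the genes with the largest rises and falls, those whose genotype effect passed with opposite signs at successive stages were as follows, and other genes were not searched. From GV to MII, Khdc3 went from -0.71 to 4.27 (difference 4.97, adjusted p = 4.15e-08) and Dppa5a from -0.84 to 4.01 (4.85, adjusted p = 5.29e-08). Mcee, a mitochondrial epimerase gene, went from -1.77 to 3.58 (5.35, adjusted p = 5.43e-05) and the chemokine gene Ccl2 from -1.82 to 1.40 (3.23, adjusted p = 0.00037). In the other direction Malat1 went from 3.40 to -1.36 (-4.76, adjusted p = 6.26e-07) and the proteoglycan gene Srgn from 2.58 to -1.32 (-3.89, adjusted p = 1.15e-05). From MII to zygote the lysosomal enzyme gene Naglu went from -0.77 to 0.65 (1.42, adjusted p = 0.021). From zygote to 2-cell, Btg4 went from -1.94 to 1.76 (3.71, adjusted p = 8.23e-09) and Btn1a1 from -3.16 to 1.10 (4.25, adjusted p = 1.4e-05). Over the same step Depdc7 went from -2.53 to 2.03 (4.57, adjusted p = 2.37e-08), Smim11 from -4.77 to 2.81 (7.59, adjusted p = 1.33e-05) and Sycp3 from -3.66 to 1.58 (5.23, adjusted p = 1.18e-06). Cd63 went from 1.02 to -7.50 (-8.52, adjusted p = 7.13e-09).

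Genes that fell at least 2-fold in the wild-type pair of the Erk experiment had a median of 0.80 (log2) in the Btg4 comparison at MII and exceeded other genes by 1.33. A transcript length trend between libraries is argued against as the whole cause. Genes were ranked by transcript length and cut into 10 bins of equal gene number. Within these bins the excess was 1.26 (median, 0.74 to 1.60 over 8101 genes). It was lowest, at 0.74, in the bin of the longest transcripts. Relative scaling stays open for the level of these genes, whose median was 0.55 ± 0.054 (SD) with median-of-ratios scaling against a bound of 0.5. Slower loss of maternal transcripts stays open, as a hypothesis, because its tests depend on the stage labels of the Btg4-/- libraries. The excess was -0.081 at GV. From GV to MII the set changed relative to other genes by 0.795 ± 0.02 in labelled Btg4-/- and by -0.45 ± 0.069 in wild type. As labelled, slower loss is thus not the whole cause. With GV and MII exchanged within Btg4-/-, the change from GV to MII there is -0.795. The excess is then 0.73 at GV and 0.33 at MII, so that the larger part of it lies at GV. A change in poly(A) tail length, which mRNA purification would read as a change in amount, was not tested and stays open.

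The change from GV to MII in wild type was not the same in the experiments: Ldhb stood at 51.2 FPKM in wild-type GV of the Btg4 experiment and at 6619 in that of the Erk experiment, Nlrp5 at 2.37 and 1172, and Btg4 rose from 216 to 2987 in the latter but fell from 1561 to 411 in the former. An exchange of the GV and MII labels in wild type is argued against, since the changes correlated positively across 8688 genes (r = 0.185, 0.167 to 0.197 over the choices of replicates), although the MII libraries ranked genes more like the Erk wild-type GV library than the GV libraries did (rho 0.609 against 0.576), as they did for its MII library (0.588 against 0.398). A length trend is argued against, as r was 0.148 after its removal in both. An exchange within the libraries labelled Btg4-/- alone stays open: their MII libraries ranked 12311 genes less like wild-type GV than their GV libraries did (difference of rho -0.11, -0.12 to -0.09), but their change had r = -0.344 with that of the Erk wild type, with rho 0.620 against 0.537 for the Erk GV library and 0.230 against 0.386 for its MII library. No biological explanation was tested, and how the oocytes of each experiment were staged and collected stays open.

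Transcripts that rise at the 2-cell stage in wild type stayed low in the libraries labelled Btg4-/-, with a median zygote to 2-cell change of 0.055. With median-of-ratios scaling the change of the 2619 genes was 0.13 ± 0.02 (SD), and 0.12 where the set was chosen again under that scaling. This cannot decide on dilution by retained maternal transcripts, which stays open. The scaling moves all genes of a library by a single factor. Its log2 was 0.342 and 0.317 in the labelled Btg4-/- zygote libraries and 0.116 and 0.144 at 2-cell. That factor comes from genes above 1 FPKM in all 16 libraries and does not measure mRNA per embryo. A length trend is argued against as the whole cause, as the change was 0.24 ± 0.009 over 2398 genes with the length correction. Embryos behind wild type in the transition stay open as a hypothesis. In the labelled Btg4-/- embryos, 2852 genes that fell in wild type by a median of -1.72 changed by -0.63, a ratio of 0.365. These genes were chosen on the same wild-type libraries, which by itself lowers the ratio. Slower loss of maternal transcripts without a delay would lower it as well, so the ratio cannot tell the 2 apart. A poly(A) tail effect was not tested and stays open. These readings take the zygote and 2-cell labels of the Btg4-/- libraries as given, and those labels were not tested. The zygote to 2-cell change in these libraries had Pearson r = 0.496 across genes with the Erk wild-type GV to MII change. For the wild-type zygote to 2-cell change this r was 0.04.

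Other versions of these tests were replaced or dropped. For scaling at MII they were 1.11 ± 0.089 (SD) for the set chosen on the same wild-type libraries, and the excess over other genes, 1.30 ± 0.062, which a factor per library cannot move. For the 2-cell risers they were the genotype difference at 2-cell, -1.49 with median-of-ratios scaling and -1.26 with the length correction, against -1.31 as deposited. The exchange within the labelled Btg4-/- libraries and slower loss were at first judged by the differences at -0.11 and -0.081 alone.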

How the results depend on the processing

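The fit without the GV libraries, the length correction and the list tests without 1 library were chosen after the data were seen, and the other settings before. In the labelled Btg4-/- libraries, genes that fell in wild type from GV to MII had a median change of -0.47, and those that rose from zygote to 2-cell one of 0.055. For sets chosen at 4-fold these were -0.94 and 0.20. With pseudocount 5 the latter was 0.11. Without the filter 4 lists passed at GV, against 2, and with the filter at 5 FPKM 1 passed and the 2-cell riser median was 0.18. Median-of-ratios scaling gave 369 higher and 400 lower genes at GV and medians of -0.83 and 0.12. Quantile normalization gave 299 lower genes at GV and medians of -0.68 and 0.21. The fit on the compared groups alone, with fewer degrees of freedom, gave 0 higher and 0 lower genes at GV by limma (2956 at an unadjusted p under 0.05), and 1640 and 1795 at 2-cell. It gave 1161 from MII to zygote in wild type and 659 in labelled Btg4-/-. Its riser median was 0.098 and 1 list passed at GV. The length correction gave 287 and 424 genes at GV, medians of -0.78 and 0.24, 1 list at GV and 3 for the difference from GV to MII. With an estimated correlation 0 lists passed in each of the 4 genotype contrasts (from 2, 5, 5 and 7), in MII against GV in wild type (from 4) and labelled Btg4-/- (from 4), and in their difference (from 5). For ribosomal proteins at 2-cell, called in neither direction as deposited, the signed -log10 of the camera p was -2.48 with quantile normalization and -1.6 with the length correction. The cause was not tested.

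Without 1 library, a group's lone sample is assumed to vary like the other groups. Counts of higher and lower genes then ranged from 53 to 245 and 209 to 987 at GV, 3009 to 3663 and 2391 to 2931 at MII, 2379 to 3090 and 2328 to 2972 in the zygote, and 2465 to 2778 and 2846 to 3272 at 2-cell. Changed genes ranged from 5626 to 6833, 2015 to 3770 and 6066 to 7182 for the successive steps in wild type, and 4614 to 5820, 801 to 2191 and 4548 to 5958 in labelled Btg4-/-. For their difference they ranged from 4471 to 5441, 874 to 1715 and 5151 to 5923. Lists past the threshold ranged from 1 to 5 at GV (5 without labelled Btg4-/- 2, 1 without wild type 1 or 2), 5 to 7 at MII, 5 to 5 in the zygote and 6 to 8 at 2-cell. From GV to MII they ranged from 4 to 5 in each genotype and from 5 to 7 for the difference. The set medians ranged from -0.54 to -0.41 and from 0 to 0.092. The latter was 0.081 without wild-type zygote 2, 0 and 0.013 without labelled Btg4-/- 2-cell 1 and 2, and 0.036 and 0.092 without wild-type 2-cell 1 and 2. At GV 82, 89, 53 and 62 genes were higher without labelled Btg4-/- 1 and 2 and wild type 1 and 2, and 216, 209 and 265 lower without the last 3. From MII to zygote labelled Btg4-/- had 1012 and 1006 without MII 1 and 2 and 1086 and 801 without zygote 1 and 2. Wild type had 2015 without zygote 2. The difference had 874 without labelled Btg4-/- MII 2, 899 and 908 without its zygote 1 and 2, and 959 and 967 without wild-type zygote 1 and 2.

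In the Erk experiment the GV to MII medians of the falling set in wild type and labelled Erk-/-, and r between the Erk-/- and Btg4-/- changes at MII, were -2.77, -1.16 and 0.398 with pseudocount 0.1 and -1.30, -0.73 and 0.427 with pseudocount 5. They were -1.92, -0.84 and 0.375 from 1 FPKM, and -1.95, -1.01 and 0.427 with median-of-ratios scaling. Genes at 2-fold at MII were 293 lower with pseudocount 5, 3499 higher and 921 lower from 1 FPKM, and 964 lower with median-of-ratios scaling. Over 605 named gene results, 16019 checks gave 15446 with the same call, 564 that lost it, 9 that gained it and 0 of opposite sign. Over 153 list results, 3798 checks gave 3738, 23, 35 and 2. Replicate numbers did not pair the samples (r between deviations of same-numbered libraries -0.015 to 0.126), and with the number as a block the fits called 1076, 6546, 5920 and 6133 genes at the 4 stages. Mitochondrial scaling was not run, because the files used hold no mitochondrial loci. Estimated depth was 2900000 to 5300000 fragments per library, which limits weakly expressed genes most. In the simulation 57% of 2-fold changes were recovered, so an uncalled change of that size cannot be read as absent.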

Other observations

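The list tests from zygote to 2-cell and those without 1 library were not planned, and they and the comparison of expression levels between the experiments were chosen only after the data were seen.

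Some ERK feedback genes were lower at 2-cell in the libraries labelled Btg4-/-, although their list did not pass. Dusp5, a phosphatase that dampens ERK, was at 0.726 ± 1.03 FPKM against 20.3 ± 2.59 in wild type (SD, n = 2; log2 change -3.76, adjusted p = 1.55e-06). Etv5, a transcription factor downstream of growth factor signalling, was at 0.250 ± 0.354 against 7.86 ± 2.24 (-2.83, adjusted p = 5.57e-06). The list of ERK immediate-early and feedback genes had 3 higher and 9 lower of 19, likewise adjusted over the list alone (median -0.57, adjusted p = 0.0596, range over the alternatives 0.0203 to 0.148; 0.125 with an estimated correlation). In wild type, proteasome subunits had 10 rising and 21 falling from zygote to 2-cell (11 and 21 adjusted over the list alone). They did not pass as deposited (median -0.88, camera adjusted p = 0.055). The list passed as falling with pseudocount 5 (0.0493), with no filter (0.0164) and with the length correction (0.0273). Its median was -0.88, -0.99 and -1.15 without wild-type MII library 1, zygote library 2 and 2-cell library 2. Dormant maternal mRNAs fell, 13 against 5 that rose (14 and 5 adjusted over the list alone; median -1.07, adjusted p = 0.00675, and 0.185 with an estimated correlation). So did zona and oocyte-secreted genes, 8 against 0 (9 and 0 adjusted over the list alone; median -1.37, adjusted p = 0.000724, and 0.14 with an estimated correlation). In the labelled Btg4-/- embryos ribosome biogenesis genes fell over this step, 21 against 3 that rose (21 and 3 adjusted over the list alone; median -1.10, adjusted p = 0.0146, and 0.731 with an estimated correlation). So did proteasome subunits, 20 against 6 (21 and 6 adjusted over the list alone; median -0.72, adjusted p = 0.0146, and 0.731 with an estimated correlation), and maternal effect genes, 23 against 7 (23 and 8 adjusted over the list alone; median -0.94, adjusted p = 0.0171, 0.731 with an estimated correlation and 0.128 in the fit on the compared groups alone).

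Dormant maternal mRNAs fell from GV to MII in the labelled Btg4-/- oocytes, 10 against 4 that rose (10 and 5 adjusted over the list alone; median -0.82, adjusted p = 0.0039, and 0.291 with an estimated correlation), with Plat going from 813 ± 44.4 to 50.3 ± 3.39 FPKM (SD, n = 2). In wild type 9 rose and 8 fell (9 and 9 adjusted over the list alone), the median being 0.11 and the mean -0.30, and the list did not pass (adjusted p = 0.987).

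Of 4 sperm markers, 2 were higher at MII (adjusted p = 0.699 for the list), 1 was higher in the zygote (adjusted p = 0.93) and 1 was lower at 2-cell (adjusted p = 0.657). The list had adjusted p = 0.837 at GV. Of 4 blood cell markers, 2 were lower at MII (adjusted p = 0.148; 0.0217 without wild-type MII library 2), and the list had adjusted p = 0.812, 0.948 and 0.811 at GV, in the zygote and at 2-cell. Hba-a1 was at 66.1 and 44.5 FPKM in the wild-type MII libraries and at 1.15 and 0 in those labelled Btg4-/-.

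Across 8688 genes, which are not independent replicates, wild-type GV libraries of the Btg4 experiment ranked genes more like the wild-type GV library of the Erk experiment (Spearman rho 0.576 ± 0.003, SD, n = 2) than like its MII library (0.398 ± 0.006). The wild-type MII libraries also had a higher rho with that GV library (0.609 ± 0.014) than with that MII library (0.588 ± 0.007), and higher than the wild-type GV libraries had. The libraries labelled Btg4-/- at MII had rho 0.620 with that GV library and 0.230 with that MII library. In the zygote they had 0.680 and 0.272, and at 2-cell 0.613 and 0.525. Wild type had 0.649 and 0.549 in the zygote and 0.539 and 0.483 at 2-cell. Across the same genes, the zygote to 2-cell change in labelled Btg4-/- had Pearson r = 0.496 with the Erk wild-type GV to MII change. For the wild-type zygote to 2-cell change this r was 0.04. The cause was not tested.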
